A study of Homo sapiens with 37 samples.

How the data were processed

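Total RNA from human monocytes and from macrophages labelled M1 or M2 was depleted of ribosomal RNA and made into strand-specific paired-end libraries, per the labels' protocols. The cells came from buffy coats, the white cell layer of donated blood. The 37 libraries fall into 9 groups, named by the labels: monocytes (3 libraries), M1 at 18 h (4), day 3 (5), day 5 (5) and day 7 (4), and M2 at the same 4 times (4 each). The labels give neither the cytokines used nor whether replicates of a group came from separate donors, so the p-values measure the spread between these samples, which may be partly technical.

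The values are FPKM (fragments per kilobase of transcript, scaled to the library's mapped fragments), 1 value per annotated long non-coding RNA (lncRNA) transcript and library, as deposited by the authors. The submitters' processing notes list cutadapt, FastQC, Bowtie2, TopHat2 and StringTie and the build GRCh38. Their versions, roles, filters and annotation release are not given in the sources used here, and neither is whether counting used the strand. The authors' deposited values come in 2 tables, with the monocytes and M1 groups in 1 and the monocytes and M2 groups in the other. Both tables list the same 17325 transcripts, and the monocyte values are identical in 100% of rows, so the tables were joined. Protein-coding transcripts were not analysed here. Per the labels, M1 18 h replicate 1 came with 1 of its 2 read files, and its values were used as deposited.

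FPKM gives no read totals. Low values times transcript length were whole multiples of their 1st percentile in 8.1 to 17.5% of cases per library (within 0.05). That percentile stood in for 1 read, and no other unit was tried. Whole reads were not recovered this way, and the sequencing depth is unknown. No count model was used and no interval that needs a depth is given. The number of transcripts above 0 FPKM stands in for depth as a description of each library. An exact 0 can be a failed estimate, so a gene at 0 is said to be listed at 0, and no fold is given against a group listed at 0 in every library.

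Rows with 1 gene name were summed, which gave 10650 names. Of these, 14 names from the Y chromosome and the X inactivation centre were left out so that no donor's sex is reported, leaving 10636. In 3 rows the tables differed in gene name, and the second table's name was taken unless it was blank. Per gene, log2(FPKM + 0.1) was tested with limma 3.58.1 in R 4.3.3 (moderated two-sided test with a mean-variance trend, Benjamini-Hochberg adjustment over all genes tested, threshold 0.05). A gene was tested where at least 3 libraries of the fit reached 0.5 FPKM. Fold changes are on the log2(FPKM + 0.1) scale, which understates the change of low genes, and their errors are standard errors (SE). M1 groups and monocytes formed 1 fit (3465 genes), M2 groups and monocytes another (3594 genes), and all 37 libraries a joint fit (4020 genes) for M1 against M2. The comparisons were each macrophage group against monocytes, day 7 against 18 h within M1 and within M2, M1 against M2 at each time, and the difference between M1 and M2 in the change from 18 h to day 7 (an interaction contrast).

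Named genes followed a rule fixed before the data were examined, as were the tests, gene lists and alternatives below unless said otherwise. For 18 h and day 7 against monocytes and for M1 against M2 at 18 h and day 7, the rule took up to 10 genes each way with the largest log2 change among those with adjusted p under 0.05, a mean of at least 1 FPKM in the higher group and no overlap between samples. Other comparisons took 3 each way. Clone-based names were used only where fewer than 3 symbols qualified. MALAT1, NEAT1 and MIR155HG were followed throughout. From each gene list up to 4 members with the smallest p were examples. A single gene was run under the alternatives below only in comparisons where the rule named it, or throughout for the followed genes. List examples that the rule did not name were not run.

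The 22 gene lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. The 13 lists of protein-coding genes (M1-type and M2-type macrophage, monocyte, maturation and lysosome, dendritic, T and NK cell, B cell, platelet and red cell, neutrophil, lipid, proliferation, handling and ribosomal protein genes) had 0 measured members. The other 9 lists were interferon-linked, NF-kB and TLR-linked, myeloid differentiation, monocyte-associated, snoRNA host, microRNA host, abundant nuclear and housekeeping, T and NK cell, and B cell lncRNAs.

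Alternatives were a pseudocount of 1, no filter, a filter of 1 FPKM, quantile normalization, untouched transcript rows, the replicate number as a block, only the groups compared in the fit, and each library left out in turn. Chosen after seeing the data were a fit without the 6 libraries under 5000 detected transcripts and a fit with sample weights. The first leaves 2 monocyte, 4 M1 day 5, 2 M2 day 5 and 2 M2 day 7 libraries. Same-numbered samples of the groups compared deviated together, with every pair's correlation over 0.1, in 2 comparisons: M2 day 7 against monocytes (0.18 to 0.26) and M1 against M2 at day 3 (0.13 to 0.38). In M1 against M2 at 18 h, day 5 and day 7, same-numbered samples had mean correlations of 0.174, 0.101 and 0.133. Samples of other numbers had -0.058, -0.02 and -0.039. Some numbers may thus pair samples there too, which the main fits leave out. The labels do not say that a number marks a donor.

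The fits were tested on simulated data with 200 changed genes per comparison. For M1 at 18 h against monocytes (3465 genes simulated) 72% of 50 genes changed by 2 on the log2 scale were recovered and 94% of 50 changed by 4. For M2 at 18 h against monocytes (3594 genes) the shares were 4% and 50%, and for M1 against M2 at day 7 (4020 genes) 18% and 82%. Unchanged genes made up 4.2%, 7.9% and 2.5% of the simulated calls. These shares describe the simulated data and cannot be read as rates for the real libraries, which can deviate as wholes. Regrouping the real M1 and M2 day 7 samples without regard to arm gave up to 104 calls, against 25 for the real groups. Splits of the samples were drawn up to 100 per comparison with a fixed seed. Coordinates are those of the deposited tables on GRCh38, and overlapping genes were read from RefSeq for GRCh38.p14. Figures were drawn with matplotlib 3.10.9.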

Results

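The series profiled lncRNAs while human blood monocytes became M1 or M2 macrophages, the textbook names for classically and alternatively activated macrophages. Of 37 libraries, 3 were monocytes and 34 were macrophages at 18 h, day 3, day 5 or day 7. Most libraries listed 7135 to 9958 of the 17325 transcripts above 0 FPKM. The 6 exceptions were monocytes replicate 3 (4891), M1 day 5 replicate 4 (3868), M2 day 5 replicates 1 and 4 (4709 and 123) and M2 day 7 replicates 3 and 4 (3387 and 1883). A 300 bp single-exon row, AL139099.5, took 40.0 to 94.48% of the summed FPKM in 32 libraries and was near 0 in 5. It lies on chromosome 14 (49586579 to 49586878), where RefSeq places RN7SL1, the RNA of the signal recognition particle. All other rows together came to 0.939 to 0.951% of mapped fragments in monocytes (n = 3) and 0.467 to 0.85% in the macrophage libraries.

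**Figure D1:**
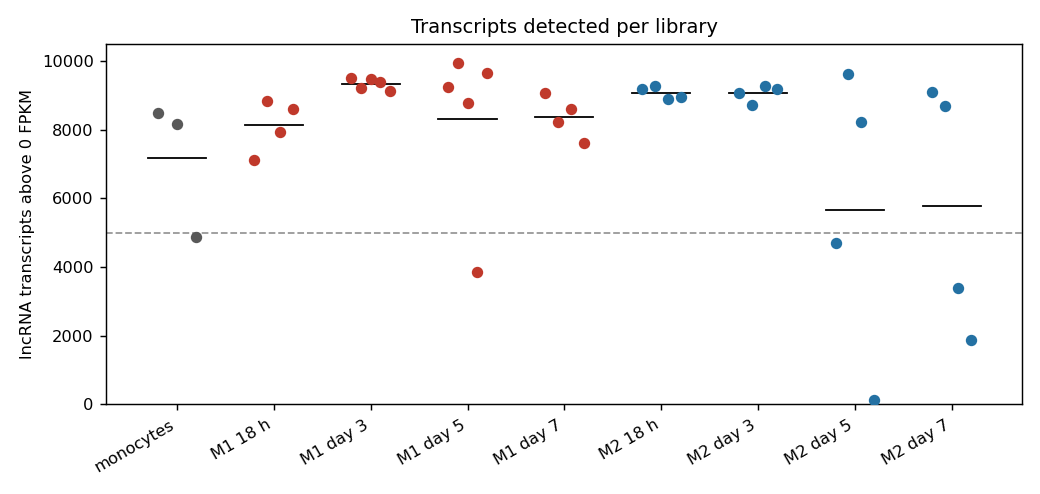
Number of lncRNA transcripts above 0 FPKM (vertical axis) in each library (points) of the 9 groups (horizontal axis), with the group mean as a bar and 5000 transcripts as a dashed line. The 6 libraries below the line hold 123 to 4891 transcripts.

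In M1 macrophages at 18 h, WFDC21P (also called lnc-DC, known from dendritic cell differentiation) stood at 11.1 to 14.6 FPKM (n = 4), against 0 to 0.0859 in the 3 monocyte libraries. Its log2 fold change was 6.44 ± 0.93 (adjusted p = 4.41e-05). JAKMIP2-AS1 (4.49 to 16.3 FPKM, adjusted p = 1.46e-08) and MSC-AS1 (2.61 to 11.1 FPKM, adjusted p = 4.38e-05) were listed at 0 in all 3 monocyte libraries. GK-AS1, antisense to the glycerol kinase gene, rose by 4.65 ± 1.09, and LINC00622, CASC19 and DOCK4-AS1 rose by 4.42 ± 0.79, 4.17 ± 0.69 and 4.09 ± 0.57. LINC01705, LINC02345 and LINC01010, listed at 0 in monocytes, were also higher (adjusted p = 0.00129, 1.53e-05 and 7.31e-06).

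LINC00528 fell in M1 at 18 h. It went from 21.8 ± 2.25 FPKM (SD, n = 3) to 0.674 ± 0.189 (n = 4), a log2 fold change of -4.85 ± 0.69 (adjusted p = 3.98e-05). ATP2B1-AS1 went from 29.5 ± 7.96 to 1.03 ± 0.129 FPKM (-4.68 ± 0.36, adjusted p = 1.46e-08). LINC00173, a transcript linked to granulocyte differentiation, changed by -4.71 ± 0.75 and TNK2-AS1 by -4.56 ± 0.48. FAM157C, ADORA2A-AS1, DNMBP-AS1, LINC00167, MIR194-2HG and LDLRAD4-AS1 followed with log2 changes of -4.42 to -3.33. LINC00528 (chromosome 22, 17777322 to 17779481) and ATP2B1-AS1 (chromosome 12, 89708959 to 89712590) are single-exon rows, and the second overlaps the start of the calcium pump gene ATP2B1. Whether counting used the strand is not given, so reads of an antisense transcript and its partner gene cannot be separated here. Reads of coding genes that span LINC00092 (ERCC6L2), LINC02185 (MRTFB) and AC022336.3 (ITGB5), all named below, cannot be separated either. The span of the summed LINC00877 rows also covers the RefSeq lncRNA LINC00870.

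Among the lists at 18 h in M1, 2 of 11 tested myeloid differentiation lncRNAs rose and 1 fell, WFDC21P, SMIM25 (2.40, adjusted p = 0.000561) and LINC00173. SMIM25, which RefSeq calls PELATON, went from 20.9 ± 12.8 FPKM to 97.3 ± 15.2. Of 7 NF-kB and TLR-linked lncRNAs 1 rose, MIR3142HG, the host of miR-146a (3.85, adjusted p = 0.0023), and 3 fell: LINC00528, PACERR beside PTGS2 (-2.34, adjusted p = 0.00855) and NKILA (-1.80, adjusted p = 0.0171). Of 13 microRNA hosts 2 rose, MIR3142HG and MIR17HG (3.09, adjusted p = 0.00428), and 2 fell, MIR646HG and MIR22HG. Adjusted over the list alone the counts in these 3 lists were the same. Of 20 snoRNA hosts 1 rose and 1 fell (0 and 0 adjusted over the list alone), of 7 monocyte-associated lncRNAs 1 rose (CYP1B1-AS1, 3.40, adjusted p = 0.00105), and 0 of 3 interferon-linked ones passed. No list passed the camera test (smallest adjusted p = 0.999). In all 979 of 3465 genes were called, 467 higher and 512 lower (more higher than lower under 5 of 16 alternatives), and 1381 had an unadjusted p under 0.05. With sample weights, chosen after seeing the data, 1490 were called.

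At day 3 and day 5 in M1, LINC00528 was lower by -5.46 ± 0.66 and -5.45 ± 0.66 on the log2 scale, ATP2B1-AS1 by -5.18 ± 0.35 and -5.43 ± 0.35 and TNK2-AS1 by -4.78 ± 0.46 and -4.69 ± 0.46, against monocytes. WFDC21P (7.57 ± 3.16 FPKM, n = 5), MIR34AHG, the host of miR-34a, and LINC02185 were higher at day 3, with log2 changes of 5.57 ± 0.89 for WFDC21P and 4.39 ± 0.87 for LINC02185. MIR34AHG was listed at 0 in monocytes (adjusted p = 0.00274). At day 5 LINC01010 (1.02 to 3.47 FPKM, listed at 0 in monocytes), GAPLINC (4.18 ± 0.74, adjusted p = 0.000212) and LINC02345 were higher. So was the clone-named AL109754.1, singled out after its values were seen and listed at 0 in monocytes, at both times (3.86 ± 0.951 and 5.94 ± 2.06 FPKM, adjusted p = 2.28e-08 and 6.19e-09). Day 3 had 1299 calls (845 higher, 454 lower; 590 and 559 after quantile normalization) and day 5 had 1178 (584 higher, 594 lower; more higher than lower under 7 of 17 alternatives). Of 11 myeloid differentiation lncRNAs 5 were higher and 2 lower at day 3, and 5 and 3 at day 5 (the same counts adjusted over the list alone). Of 7 NF-kB and TLR-linked ones 2 were higher and 2 lower at day 3 (2 and 3 adjusted over the list alone) and 2 and 3 at day 5, with PACERR at -2.89 and -3.45. Of 13 microRNA hosts 4 were higher and 2 lower at day 3, and 3 and 3 at day 5 (4 and 3 adjusted over the list alone), MIR22HG falling at both times (-3.12 and -3.21). Of 7 monocyte-associated lncRNAs 1 was higher and 1 lower at each time (the same counts adjusted over the list alone). No list passed camera at either time (smallest adjusted p = 0.901 and 0.798). A filter of 1 FPKM left 838 at day 3, a fit of only the groups compared left 605 at day 5, and sample weights gave 1825 at day 5.

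By day 7 in M1, GAPLINC (chromosome 18, 3466250 to 3478978), a lncRNA first described in gastric cancer, had reached 8.92 ± 1.38 FPKM (n = 4) against 0 to 0.205 in monocytes, a log2 fold change of 5.95 ± 0.78 (adjusted p = 6.53e-06). LINC01010 (3.28 to 15.3 FPKM, adjusted p = 4.71e-08) and LINC00092 (1.29 to 4.70 FPKM, adjusted p = 6.26e-07) were listed at 0 in monocytes. FAM95B1, MIR3142HG, PCED1B-AS1 and ZBED3-AS1 rose by 4.45 ± 0.58, 4.34 ± 0.87, 3.65 ± 0.74 and 3.54 ± 0.46, and MIR34AHG, LINC02345 and JAKMIP2-AS1 were higher than a monocyte level of 0. LINC00528 (-6.35 ± 0.69), LINC00877 (-5.33 ± 0.63), ATP2B1-AS1 (-5.33 ± 0.36), ADORA2A-AS1 (-4.81 ± 0.59) and LINC00173 (-4.51 ± 0.75) fell, as did TNK2-AS1, DNAJB5-AS1, KRTAP5-AS1, LINC00167 and LINC02384. KRTAP5-AS1 and LINC02384 were listed at 0 in all 4 M1 libraries.

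Of 11 myeloid differentiation lncRNAs 4 were higher at day 7 in M1, among them GAPLINC and MIR99AHG, and 3 lower, among them LINC00877 and LINC00173 (5 and 4 adjusted over the list alone). MIR99AHG was listed at 0 in all monocyte libraries (adjusted p = 0.000169). The NF-kB and TLR-linked list had 2 of 7 higher, among them MIR3142HG, and 4 lower, among them LINC00528, PACERR and LINC-PINT (-3.24, adjusted p = 0.0038), also when adjusted over the list alone. Of 13 microRNA hosts 4 rose and 2 fell (4 and 4 adjusted over the list alone). Of 20 snoRNA hosts 3 fell (SNHG15, SNHG7 and EPB41L4A-AS1), and of 7 monocyte-associated lncRNAs LINC00877 and LINC00937 fell while CYP1B1-AS1 rose (the same counts adjusted over the list alone for both). No list passed camera (smallest adjusted p = 0.845). Day 7 had 1055 calls, 453 higher and 602 lower (498 and 491 after quantile normalization), and 643 when only the groups compared were fitted.

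**Figure D2:**
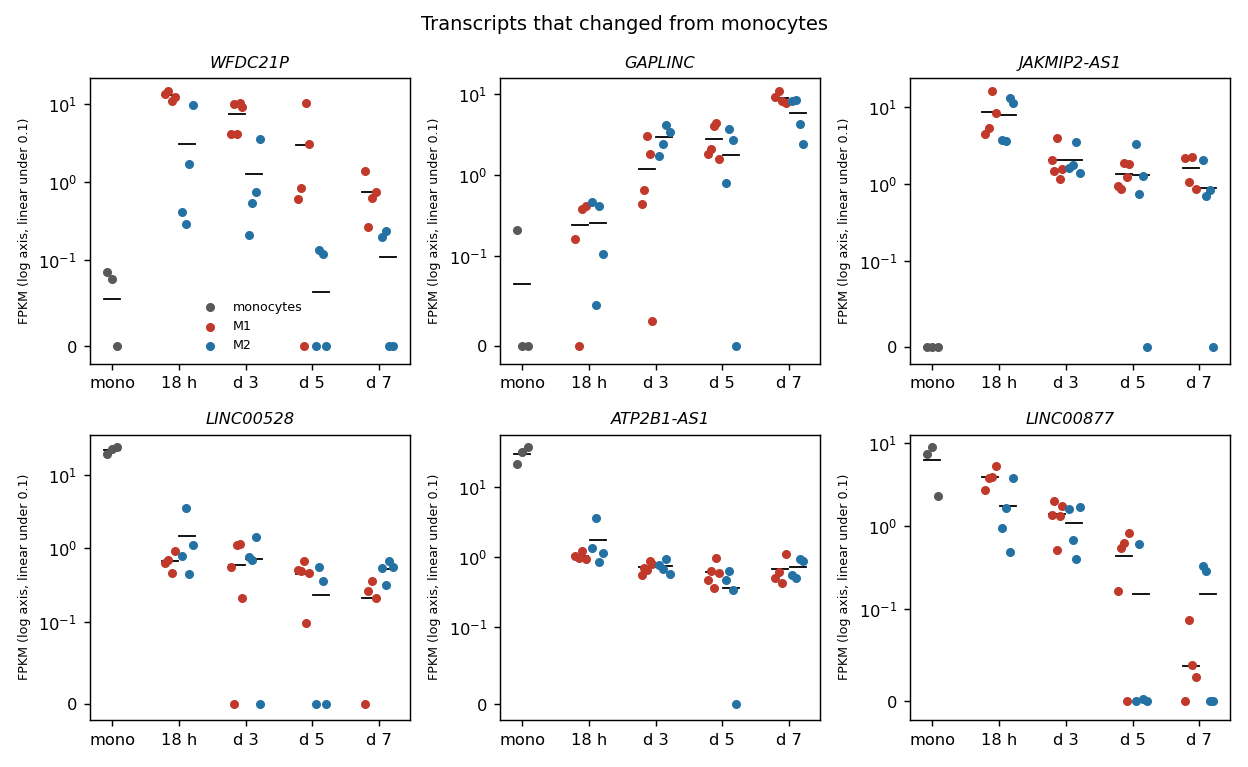
FPKM (vertical axis, logarithmic above 0.1 and linear below) of 6 lncRNAs in each library (points) of monocytes (grey), M1 (red) and M2 (blue) by time (horizontal axis), with group means as bars. LINC00528 lies at 19.3 to 23.5 FPKM in monocytes and at 3.53 or below at 18 h in both arms, and GAPLINC reaches 7.64 to 10.7 in M1 at day 7.

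Between 18 h and day 7 in M1, single transcripts changed in both directions. GAPLINC rose by 4.99 ± 0.72 on the log2 scale (adjusted p = 0.000114), PCED1B-AS1 by 4.16 ± 0.69 (4.41 to 7.11 FPKM at day 7), and FAM95B1 by 4.00 ± 0.53. MIR3945HG went from 8.76 ± 2.87 FPKM at 18 h to 0 to 0.271 at day 7 (-5.62 ± 0.83, adjusted p = 0.000154), LINC00877 from 3.89 ± 1.04 to 0 to 0.0880 (-4.85 ± 0.58) and CASC19 from 1.15 to 4.64 down to 0 to 0.0183 (-4.18 ± 0.64). Of 11 myeloid differentiation lncRNAs 3 rose, among them GAPLINC and LINC01094 (3.48, adjusted p = 0.000233), and 2 fell, among them LINC00877 (the same counts adjusted over the list alone). Of 4 T and NK cell lncRNAs CD27-AS1 (1.35, adjusted p = 0.00915) and TRG-AS1 (1.54, adjusted p = 0.0362) rose and LINC02384 (adjusted p = 0.0139) fell, and of 2 B cell lncRNAs LINC00926 fell (-2.03, adjusted p = 0.00401; the same counts adjusted over the list alone). AL109754.1, also given outside the naming rule, rose from 0.458 ± 0.336 to 11.3 ± 2.30 FPKM (4.57 ± 0.41, adjusted p = 3.66e-07). Of 3465 genes 372 were called, 177 higher and 195 lower (more higher than lower under 5 of 17 alternatives). Without M1 18 h replicate 4 there were 215, with quantile normalization 566, with sample weights 720, and 795 without the 6 libraries under 5000 transcripts.

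In M2 macrophages at 18 h, JAKMIP2-AS1 (3.64 to 13.3 FPKM, adjusted p = 0.000153), LINC01010 (1.28 to 8.26, adjusted p = 0.00507), LINC01705 (0.698 to 7.95, adjusted p = 0.000294) and MSC-AS1 (adjusted p = 0.000701) were higher, all listed at 0 in monocytes. GK-AS1 rose by 5.02 ± 1.13 to 12.3 ± 7.50 FPKM (n = 4). LINC02185, MIR3142HG, ARHGAP22-IT1, C1orf195 and MAGI2-AS3 rose by 4.49 to 4.11. TNK2-AS1 (-4.58 ± 0.68, adjusted p = 2.05e-05), ATP2B1-AS1 (-4.20 ± 0.94, to 1.72 ± 1.28 FPKM), LINC00528 (-4.17 ± 0.98, to 1.47 ± 1.40 FPKM) and LINC00173 (-4.12 ± 0.90) fell. HLA-DQB1-AS1, MIR194-2HG, FAM157C, LINC00167, ADORA2A-AS1 and LINC00484 fell by log2 changes of -4.05 to -3.09.

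Among the lists at 18 h in M2, 1 of 10 myeloid lncRNAs rose (WFDC21P, 0.287 to 9.82 FPKM, adjusted p = 0.0277) and 1 fell (LINC00173), and of 6 NF-kB and TLR-linked ones MIR3142HG rose and LINC00528 fell (1 and 2 adjusted over the list alone). LUCAT1, a stress and interferon-response transcript, was the 1 of 4 interferon-linked lncRNAs that rose (2.56, adjusted p = 0.0298). Of 10 microRNA hosts MIR3142HG and MIR17HG rose, and 0 of 20 snoRNA hosts passed. No list passed camera (smallest adjusted p = 0.563). In all 181 of 3594 genes were called (97 higher, 84 lower, with more lower than higher under 9 of 16 alternatives; 746 with an unadjusted p under 0.05), and 1089 (619 higher, 470 lower) without the 6 libraries under 5000 transcripts, none of which is an M2 18 h library. Leaving out monocytes replicates 1, 2 and 3 gave 48, 50 and 69 calls, and leaving out M2 replicates 2, 3 and 4 gave 118, 57 and 70. LINC00528 lost its call without M2 replicate 3 (adjusted p = 0.0581, 2.22e-06 to 0.0581 over the alternatives), GK-AS1 without monocytes replicate 3 (0.0661, 1.84e-05 to 0.0661) and LINC00173 without monocytes replicate 2 (0.058, 1.07e-07 to 0.058). LINC01010 (to 0.0519), LINC02185 (to 0.0591), MIR3142HG (to 0.0587), ARHGAP22-IT1 (to 0.122), C1orf195 (to 0.13), HLA-DQB1-AS1 (to 0.172), FAM157C (to 0.122), LINC00167 (to 0.0682), ADORA2A-AS1 (to 0.209) and LINC00484 (to 0.0581) also lost theirs under at least 1 alternative.

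At day 3 in M2, LINC02185 (4.48 ± 3.22 FPKM, n = 4), MIR3142HG and C1orf195 rose, with log2 changes of 4.97 ± 1.10, 4.69 ± 1.07 and 4.68 ± 1.18, and LINC00528 (-5.26 ± 0.98), ATP2B1-AS1 (-5.14 ± 0.94) and TNK2-AS1 (-4.81 ± 0.68) fell. At day 5, LINC00528 (-6.54 ± 0.98), ATP2B1-AS1 (-6.31 ± 0.94) and LINC00937 (-5.51 ± 0.95) fell. Clone-named rows rose at day 5, AC022336.3 (0.137 to 84.7 FPKM, listed at 0 in monocytes), AC245060.6 (3.64 ± 0.95) and AC008622.2 (3.54 ± 1.14). AC022336.3 and AC008622.2 lost their calls without M2 day 5 replicate 4, the library of 123 transcripts, which brought the log2 change of AC008622.2 to 1.37 (adjusted p = 0.0668 and 0.138, with 0.000135 to 0.111 and 0.0101 to 0.222 over the alternatives), and AC245060.6 without monocytes replicate 2 (adjusted p = 0.0548, 2.86e-05 to 0.0995). Without the 6 libraries AC008622.2 and AC245060.6 stood at 1.12 and 2.38. At day 3 C1orf195 lost its call without monocytes replicate 1 or 2 (adjusted p = 0.0799 and 0.0672, 6.44e-09 to 0.0799). Of 6 NF-kB and TLR-linked lncRNAs 1 was higher and 2 lower at day 3 (2 and 2 adjusted over the list alone), and 0 and 4 at day 5 (1 and 4), PACERR falling at both times (-2.77 and -3.01). Of 7 monocyte-associated ones 1 fell at day 3 (LINC00937; 2 higher and 2 lower adjusted over the list alone) and 3 at day 5 (LINC00937, LINC00877 and VCAN-AS1; 0 and 4). No list passed camera (smallest adjusted p = 0.781 and 0.197). Day 3 had 282 calls (135 higher, 147 lower; more higher than lower under 4 of 16 alternatives) and day 5 had 483 (37 higher, 446 lower; 321 and 388 after quantile normalization). Without the 6 libraries they were 1338 (784 higher, 554 lower) and 1146 (577 higher, 569 lower), and each left-out library lowered the day 3 count, to 55 (monocytes replicate 2), 81 and 136 (monocytes replicates 1 and 3) and 138, 148, 151 and 174 (M2 replicates 1 to 4). At day 5 there were 225 and 198 without monocytes replicates 1 and 2.

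By day 7 in M2, LINC01857 (chromosome 2, 207662375 to 207667024), a member of the fixed B cell list, stood at 11.3 ± 8.99 FPKM (n = 4) against 0 to 0.143 in monocytes, a log2 fold change of 5.79 ± 1.22 (adjusted p = 0.000814). LINC01010 (1.82 to 14.7 FPKM) was again listed at 0 in monocytes, and GAPLINC reached 5.79 ± 2.94 FPKM (5.18 ± 1.01, adjusted p = 0.000363). MIR3142HG, TM4SF19-AS1, LINC00891 and ZBED3-AS1 rose by 4.97 ± 1.07, 3.82 ± 1.06, 3.75 ± 0.88 and 3.67 ± 1.09, followed by LINC02344, STEAP3-AS1 and FAM95B1. LINC00167 (-5.22 ± 0.85), ATP2B1-AS1 (-5.19 ± 0.94), LINC00528 (-5.17 ± 0.98), LINC00937 (-5.04 ± 0.95) and C1RL-AS1 (-4.76 ± 0.91) fell, as did LINC00877, TNK2-AS1, LINC01619, USP3-AS1 and ADORA2A-AS1.

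Of 7 monocyte-associated lncRNAs 4 fell in M2 at day 7 (LINC00937, LINC00877, VCAN-AS1 and LINC02432; also 4 adjusted over the list alone). The list's camera test gave adjusted p = 0.0234, and adjusted p = 0.805 with an estimated correlation. It passed under none of the 4 alternatives run for lists (0.0587 to 0.805). Of 10 myeloid lncRNAs GAPLINC rose and LINC00877 and LINC00173 fell, and of 6 NF-kB and TLR-linked ones MIR3142HG rose and LINC00528 and PACERR fell (1 and 3 adjusted over the list alone). Of 20 snoRNA hosts SNHG15 (-3.52, adjusted p = 0.0274) and SNHG9 fell, and PSMB8-AS1 was the 1 of 4 interferon-linked lncRNAs that fell (-3.98, adjusted p = 0.0214). Day 7 had 463 calls (67 higher, 396 lower; 313 and 354 after quantile normalization). Without the 6 libraries, of which 3 enter this contrast, there were 1169 (492 higher, 677 lower), without monocytes replicate 2 there were 169, and without monocytes replicate 1 there were 194. TM4SF19-AS1 lost its call without monocytes replicate 1 (adjusted p = 0.0591, 0.000168 to 0.0591 over the alternatives), STEAP3-AS1 without replicate 2 (0.0585, 2.41e-05 to 0.0585), ZBED3-AS1 without any 1 of the 3 (0.0586 to 0.116, with 3.08e-06 at the lowest) and LINC02344 under 7 of 15 alternatives (4.64e-05 to 0.239).

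**Figure D3:**
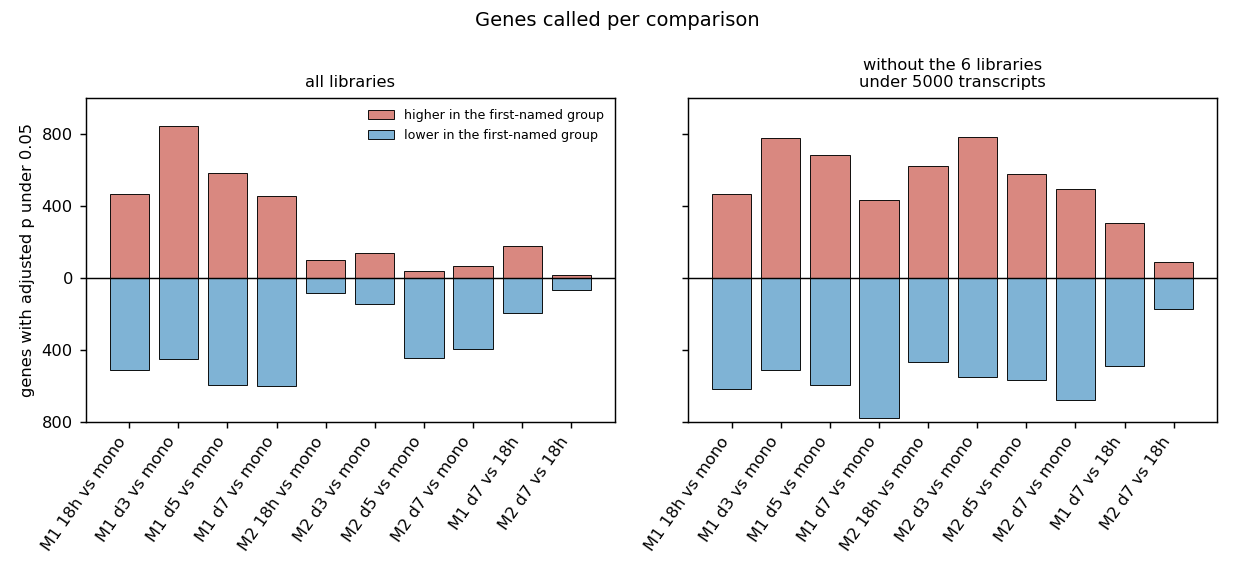
Genes with adjusted p under 0.05 (vertical axis, higher above and lower below 0) in 10 comparisons (horizontal axis), with all libraries (left) and without the 6 libraries under 5000 transcripts (right). M2 at 18 h goes from 181 to 1089 calls while M1 at 18 h goes from 979 to 1089.

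From 18 h to day 7 in M2, GAPLINC rose by 4.12 ± 0.93 (adjusted p = 0.00937), as it did in M1, and the clone-named AC005632.2 (4.35 ± 0.99) and AC026369.3 (4.00 ± 1.10) rose with it. GK-AS1 fell from 12.3 ± 7.50 FPKM to between 0 and 2.55 (-4.75 ± 1.05), SNHG25, a snoRNA host, from 5.64 to 84.1 down to 0 to 5.02 (-4.72 ± 1.25), and LINC01705 by a log2 change of -4.39 ± 0.86. Of 20 snoRNA hosts SNHG9 and SNHG25 fell (3 adjusted over the list alone). CYP1B1-AS1 fell among 7 monocyte-associated lncRNAs (-3.66, adjusted p = 0.04725, 5 adjusted over the list alone). PSMB8-AS1 fell among 4 interferon-linked lncRNAs (-4.33, adjusted p = 0.0243, 2 adjusted over the list alone). MIR17HG fell among 10 microRNA hosts (-3.78, adjusted p = 0.0116). GAPLINC rose and WFDC21P fell among 10 myeloid lncRNAs. Of these list members only GAPLINC and SNHG25 were run under the alternatives. At day 7, where M2 replicates 3 and 4 listed 3387 and 1883 transcripts, CYP1B1-AS1 ranged from 0.000218 to 2.75 FPKM. PSMB8-AS1 ranged from 0 to 2.74 and MIR17HG from 0 to 0.982. The camera test passed for no list (smallest adjusted p = 0.0572). Of 3594 genes 82 were called, 14 higher and 68 lower (138 and 81 after quantile normalization). Without the 6 libraries 262 were called, and the calls of AC005632.2, SNHG25 and LINC01705 ended (adjusted p = 0.0982, 0.115 and 0.0508, with 0.00101 to 0.103, 0.00484 to 0.17 and 0.00026 to 0.0508 over the alternatives), with log2 changes of 3.36, -1.975 and -3.62, and GK-AS1 went to -2.79. Sample weights gave SNHG25 -1.95 and LINC01705 -2.675. GAPLINC lost its call without M2 18 h replicate 2 (0.0699, 2.44e-06 to 0.0699), GK-AS1 without M2 day 7 replicate 3 (0.0587, 0.00044 to 0.0626) and AC026369.3 under 6 of 16 alternatives (0.00158 to 0.168). Leaving out M2 18 h replicates 1 to 4 gave 54, 26, 42 and 37 calls, and leaving out M2 day 7 replicates 1, 3 and 4 gave 243, 31 and 50.

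Calls against monocytes overlapped between the arms. At 18 h, 82 genes were higher in both M1 and M2 (431 and 88 of the 3222 genes tested in both) and 74 lower in both (505 and 76; more lower than higher in both under all 3 alternatives run), with 0 called in opposite directions. WFDC21P, JAKMIP2-AS1 and GK-AS1 were among the first and LINC00528, ATP2B1-AS1 and TNK2-AS1 among the second. Independent lists of those sizes would share 11.8 and 11.9 genes. At day 7, 46 were higher in both (421 and 55; 7.2 for independent lists), among them GAPLINC and LINC01010, 290 were lower in both (592 and 365; 67.1), among them LINC00528 and LINC00877, and 0 were opposite. After quantile normalization day 7 had 192 higher and 258 lower in both, and without the 6 libraries 739 genes were called in both arms at 18 h and 810 at day 7. Across genes, which are not independent replicates, the log2 changes had a covariance of 2.174 at 18 h and 2.384 at day 7. In 100 simulations of unchanged groups that shared 3 simulated monocyte libraries it was 0.394 and 0.398, a difference of 1.779 and 1.986. The simulated noise was independent between genes, so deviations of whole libraries are not in it. The correlations were 0.932 and 0.874, beside 0.57 and 0.574 simulated. The simulated number called in both averaged 0, which says little, since the adjustment leaves few calls in unchanged groups. The 3 shared monocyte libraries are too few to split, so part of the excess may come from them.

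M1 and M2 differed directly in few genes at 18 h. MIR3945HG, the host of miR-3945, stood at 8.76 ± 2.87 FPKM in M1 (n = 4) and 0.690 ± 0.439 in M2 (n = 4), a log2 difference of 3.62 ± 0.77 (adjusted p = 0.0141). INHBA-AS1, which overlaps the activin A subunit gene INHBA, stood at 1.86 ± 0.981 and 0.125 ± 0.138 FPKM (3.17 ± 0.61, adjusted p = 0.00412). CASC19 (chromosome 8, 127116660 to 127227541) stood at 2.21 ± 1.63 and 0.147 ± 0.0242 FPKM (3.01 ± 0.56, adjusted p = 0.00311). The span of its summed rows also covers the RefSeq lncRNA CCAT1. All 4 M1 libraries lay above all 4 M2 libraries for MIR3945HG, INHBA-AS1 and CASC19, which the naming rule required. Of 4020 genes 9 were called, all higher in M1, and 131 had an unadjusted p under 0.05. Of 12 myeloid lncRNAs 0 were called (1 higher adjusted over the list alone), while the list's camera test gave adjusted p = 0.0467, or adjusted p = 0.981 with an estimated correlation (0.388 after quantile normalization, 0.0774 without the 6 libraries). Leaving out M2 18 h replicate 1 gave 5 genes and ended the call of MIR3945HG (adjusted p = 0.12), as did leaving out M1 replicate 3 (0.0829) or M2 replicate 3 (0.0627), over a range of 9.37e-07 to 0.12. The count was 29 (16 higher, 13 lower) without the 6 libraries, 22 without a filter, 16 with quantile normalization, 38 with sample weights and 4 with only the groups compared.

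At day 3 the differences between M1 and M2 were led by clone-named transcripts. AL109754.1 stood at 3.86 ± 0.951 FPKM in M1 (n = 5) and at 0 to 0.201 in M2 (n = 4), a log2 difference of 4.69 ± 0.47 (adjusted p = 4.2e-09). It is a row of 2 exons on the plus strand of chromosome 20 (9986088 to 10007116), where RefSeq lists the lncRNA PARAL1. AC055720.1 (0.472 to 4.59 against 0 to 0.0858 FPKM) and AC012653.2 differed by 4.33 ± 0.73 and 3.63 ± 0.73. All 10 called genes were higher in M1 (12 higher and 4 lower after quantile normalization). AC012653.2 lost its call without M1 day 3 replicate 1 or M2 day 3 replicate 2 (adjusted p = 0.0533 and 0.0564, 5.53e-05 to 0.0564 over the alternatives). Without M2 day 3 replicate 2 there were 5, with a filter of 1 FPKM 6, with sample weights 116, and 32 (22 higher, 10 lower) without the 6 libraries.

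At day 5 AL109754.1, given here outside the naming rule after its values were seen, was again higher in M1 (5.72 ± 0.47, adjusted p = 7.72e-12). HLA-DQB1-AS1, antisense to the MHC class II gene HLA-DQB1, stood at 9.47 ± 5.08 FPKM in M1 (n = 5) and 0 to 3.41 in M2 (n = 4), a log2 difference of 5.13 ± 0.87 (adjusted p = 0.000683). LINC00937 (0.676 to 9.64 against 0 to 0.302 FPKM, 4.04 ± 0.82) and C1RL-AS1, antisense to a complement protease-like gene (1.22 to 4.41 against 0 to 0.435 FPKM, 3.78 ± 0.69) were higher as well. The monocyte-associated list had 3 of 7 members higher in M1 (LINC00937, VCAN-AS1 and LINC02432; camera adjusted p = 0.000633, adjusted p = 0.193 with an estimated correlation). The snoRNA hosts had 0 of 20 called (camera adjusted p = 0.025, adjusted p = 0.661 with an estimated correlation and 0.738 without the 6 libraries). Day 5 had 49 calls, 47 higher and 2 lower (50 and 29 after quantile normalization), the 2 lower being AL450003.1 (-2.43) and AP000462.3 (-2.04), named after their values were seen. Of the 4 M2 libraries 2 list under 5000 transcripts: without the 6 such libraries 21 genes were called, and HLA-DQB1-AS1 and LINC00937 lost their calls at log2 differences of 3.87 and 3.00, with fewer samples (adjusted p = 0.0569 and 0.246, with 1.67e-06 to 0.0569 and 0.003 to 0.246 over the alternatives). Leaving out M1 day 5 replicates 1, 2 and 3 gave 16, 21 and 24 calls, leaving out M2 day 5 replicates 1 to 4 gave 20, 246, 172 and 29, and fitting only these groups gave 5 and ended the call of C1RL-AS1 (0.079, 0.000114 to 0.079).

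At day 7 the 23 genes higher in M1 than in M2 included AL109754.1 (8.18 to 13.7 FPKM, listed at 0 in M2, adjusted p = 1.14e-13), LINC02432 (1.97 to 8.85 against 0 to 0.645 FPKM, 4.55 ± 0.82, adjusted p = 0.00138), HLA-DQB1-AS1 (17.1 ± 3.43 FPKM against 0 to 2.10, 4.35 ± 0.92), C1RL-AS1 (0.510 to 4.45 against 0 to 0.00923 FPKM, 4.23 ± 0.73) and LINC00092 (1.29 to 4.70 against 0 to 0.261 FPKM, 3.93 ± 0.54, adjusted p = 7.85e-06). Of these, AL109754.1 was given outside the naming rule after its values were seen. LINC02345, LINC01480 and MIR3936HG were higher by 3.24 ± 0.67, 3.10 ± 0.65 and 2.84 ± 0.67. AL138924.1, which overlaps RefSeq's LINC01374, was lower in M1 (0 to 0.0739 against 0.159 to 4.26 FPKM, -3.14 ± 0.61, adjusted p = 0.00299), as was C20orf166-AS1 (-2.50 ± 0.61), named after its values were seen. The monocyte-associated list gave camera adjusted p = 1.55e-05 (adjusted p = 0.0609 with an estimated correlation), with 1 of 7 members higher and 6 adjusted over the list alone. MIR99AHG was the 1 of 13 microRNA hosts called (2.31, adjusted p = 0.033). Of 25 calls 23 were higher and 2 lower (29 and 20 after quantile normalization). Without the 6 libraries 39 genes were called (23 higher, 16 lower) and HLA-DQB1-AS1, LINC02345 and MIR3936HG lost their calls at log2 differences of 3.203, 2.19 and 1.45 (adjusted p = 0.126, 0.126 and 0.217, with 0.00106 to 0.126, 0.00214 to 0.373 and 0.00149 to 0.542 over the alternatives). With sample weights LINC02345 differed by 2.11. A fit of only the 8 libraries compared gave 1 call, AL109754.1, and ended the others (0.0732 for LINC02432, C1RL-AS1 and LINC00092, 0.324 for LINC01480 and 0.518 for AL138924.1). Leaving out M1 day 7 replicates 1, 3 and 4 gave 14, 12 and 16 calls, leaving out M2 day 7 replicate 1 gave 69, and leaving out replicate 4 gave 7 and ended the calls of HLA-DQB1-AS1 (0.116), LINC02345 (0.0627) and LINC01480 (0.0627).

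**Figure D4:**
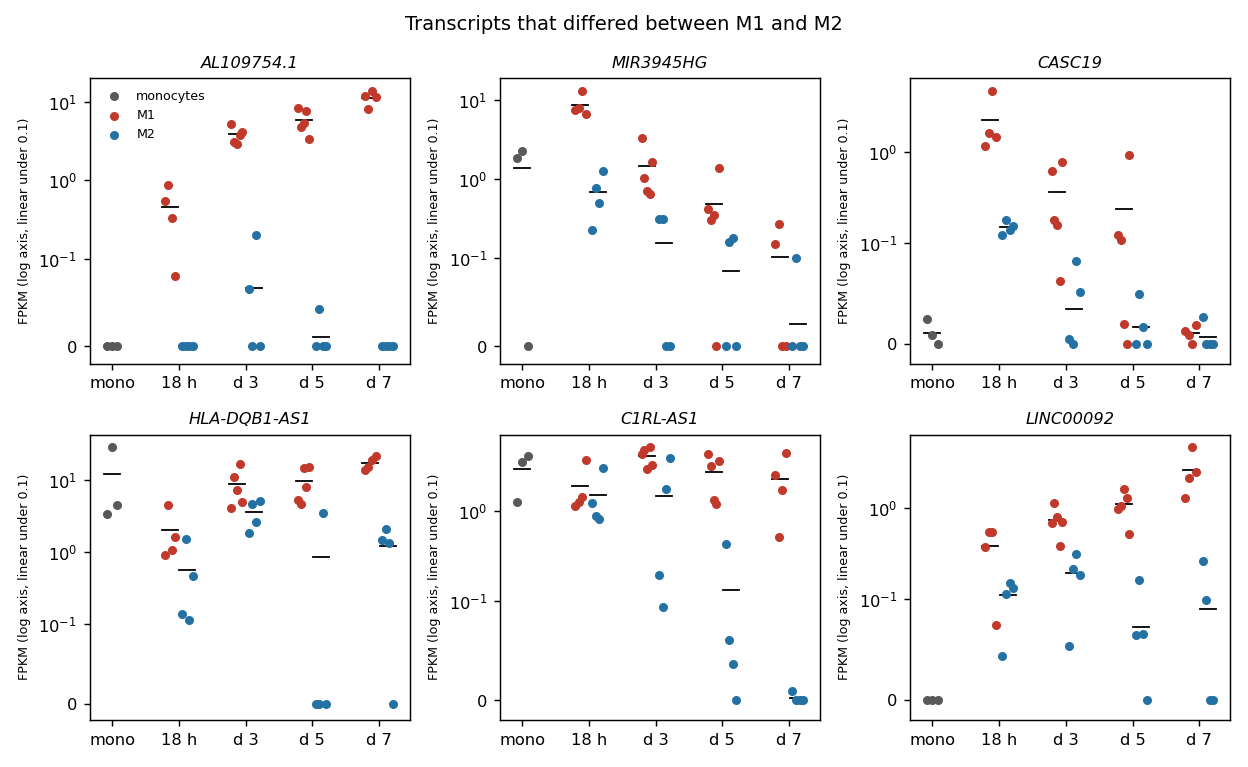
FPKM (vertical axis, logarithmic above 0.1 and linear below) of 6 lncRNAs in each library (points) of monocytes (grey), M1 (red) and M2 (blue) by time (horizontal axis), with group means as bars. AL109754.1 lies at 2.90 to 13.7 FPKM in the 14 M1 libraries from day 3 on and at 0.201 or below in the 16 M2 libraries.

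The change from 18 h to day 7 differed between M1 and M2 for 1 gene of 4020, AL109754.1 (interaction adjusted p = 0.000284), while 301 genes had an unadjusted p under 0.05. In M1 it went from 0.0803 to 0.875 FPKM at 18 h to 8.18 to 13.7 at day 7, and in M2 it was listed at 0 in all 4 libraries at both times. M1 exceeded M2 at 18 h too (adjusted p = 0.0271). For the monocyte-associated list the interaction gave camera adjusted p = 0.0121, or adjusted p = 0.525 with an estimated correlation, with 0 of 7 members called and 5 adjusted over the list alone (0.114 with a pseudocount of 1). With a pseudocount of 1 there were 7 interaction calls (3 higher, 4 lower), without a filter 2, without M2 day 7 replicate 1 also 2, and with sample weights 43.

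Of the markers of other blood cells, 3 of 4 T and NK cell lncRNAs were higher in M1 at day 3 and at day 5 (TRG-AS1, CD27-AS1 and PRKCQ-AS1) and LINC02384 was lower. At day 7 TRG-AS1 was higher in M1 (2.49 ± 0.50) and in M2 (3.18 ± 1.11). LINC02384 was lower in M2 (-3.84 ± 0.78) and in M1, where it was listed at 0 in all 4 libraries, and at day 5 in M2 (adjusted p = 0.000275), where it was also listed at 0. Of 2 tested B cell lncRNAs LINC01857 was called in M2 at day 7. These counts were the same adjusted over the list alone. At 18 h in both arms and at day 3 in M2, 0 of the 4 and 0 of the 2 were called against monocytes. Adjusted over the list alone, 1 B cell lncRNA was higher in M1 at 18 h, 1 T and NK cell lncRNA lower in M2 at 18 h, and at day 3 in M2 1 of each list higher and 1 T and NK cell lncRNA lower.

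NEAT1, the scaffold of nuclear paraspeckles, was lower than in monocytes in M1 at 18 h, day 3, day 5 and day 7 (-3.12 ± 0.73, -3.77 ± 0.70, -2.51 ± 0.70 and -2.56 ± 0.73) and in M2 at day 7 (-3.38 ± 1.15, adjusted p = 0.0433). The 3 monocyte libraries ranged from 5.73 to 66.0 FPKM. Without monocytes replicate 3 the log2 changes were smaller, at -2.09, -2.73, -1.48 and -1.525 in M1 and -2.35 in M2 at day 7, and the calls at day 5 and day 7 in M1 (adjusted p = 0.102 and 0.107, 0.00185 to 0.102 and 0.00241 to 0.107 over the alternatives) and at day 7 in M2 (adjusted p = 0.25, 0.000499 to 0.25) ended. The calls ended under 2 of 16, 4 of 15 and 8 of 15 alternatives, among them quantile normalization (adjusted p = 0.0565, 0.107 and 0.0782) and, at day 7 in M1, the fit without the 6 libraries (-1.525, adjusted p = 0.0705). At day 7 in M2 the change was -2.16 without M2 replicate 4 (adjusted p = 0.203), -1.94 after quantile normalization, -2.07 with sample weights and -1.69 without the 6 libraries, still called in the last 2 fits (adjusted p = 0.000499 and 0.0153). M2 at 18 h, day 3 and day 5 did not pass (adjusted p = 0.0928, 0.122 and 0.194), but did without the 6 libraries (-2.17, -1.64 and -1.63; adjusted p = 0.00171, 0.00688 and 0.0189; 0.000129 to 0.46, 0.000411 to 0.517 and 0.00257 to 0.598 over the alternatives). MALAT1, a nuclear speckle transcript, passed in none of the comparisons and ranged from 5.53 to 201.3 FPKM between macrophage libraries. MIR155HG, the host of miR-155, was listed at 0 in all monocyte libraries and passed in none of the comparisons that tested it. NEAT1 was 1 of 7 tested abundant nuclear and housekeeping lncRNAs, and the only one of them called in any comparison against monocytes.

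Median log2 changes over all tested genes were not 0. They were 0.104, 0.493, 0.158 and -0.016 for M1 at 18 h, day 3, day 5 and day 7 against monocytes, 0.38, 0.5, -0.474 and -0.412 for M2, -0.217 and -0.87 for day 7 against 18 h in M1 and M2, -0.276, -0.041, 0.563 and 0.35 for M1 against M2, and 0.62 for the interaction. Quantile normalization brought them to between -0.065 and 0.1, and no called change of a gene named by the rule reversed.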

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

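All tests of explanations in this part were chosen after the values had been seen. Single libraries stood apart from the rest of their group in 17 of 113 groups of 4 or 5 values. The cut-off flags about 1 in 20 groups of normally distributed values. FPKM are not such values, and any value above 0 is flagged where the others are at 0. The 17 can therefore not be set against that rate. GK-AS1 stood at 19.6 FPKM in M1 18 h replicate 4 (others 4.61 to 6.88). In M1 18 h replicate 3, CASC19 was 4.64 (others 1.15 to 1.59) and NEAT1 1.98 (1.59 to 1.65). MALAT1 was 95.6 in M1 day 3 replicate 1 (6.51 to 27.6) and 107 in M2 18 h replicate 2 (7.68 to 18.6). NEAT1 was 5.79 in M1 day 5 replicate 4 (1.58 to 2.61) and 6.73 in M2 day 5 replicate 4 (2.03 to 2.78), both libraries under 5000 transcripts. WFDC21P was 9.82 in M2 18 h replicate 4 (0.287 to 1.69), and TNK2-AS1 was 0.193 in M2 18 h replicate 3, with the others listed at 0. M2 day 5 gave 5 more: HLA-DQB1-AS1 at 3.41 in replicate 3 (others at 0), C1RL-AS1 at 0.435 in replicate 1 (0 to 0.0609), LINC00937 at 0.302 (0 to 0.00763) and AL109754.1 at 0.0426 (others at 0) in replicate 2, and AC022336.3 at 84.7 in replicate 4 (0.137 to 0.787). In M2 day 7 replicate 1, C1RL-AS1 was 0.00923 (others at 0) and LINC02432 0.645 (0 to 0.0276). M1 day 5 replicate 4 listed 3868 transcripts above 0 (8786 to 9958 in the others).

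AL109754.1 was the 1 gene whose change from 18 h to day 7 differed between the arms, with a log2 rise of 4.57 in M1 and 0 listed in M2 at both times. Few detected transcripts in M2 are argued against, because the 12 M2 libraries with at least 5000 transcripts reached at most 0.201 FPKM, while the lowest of 14 M1 libraries from day 3 on had 2.90. Reads running on from the neighbouring SNAP25-AS1 are argued against as well, since that transcript reached at most 0.053 FPKM in those M1 libraries. The coding neighbour ANKEF1 was not measured, so reads from it stay open. An M1-specific induction of this transcript, which overlaps PARAL1, is a hypothesis that remains, found and tested on the same libraries.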

How the results depend on the processing

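The fit without the 6 libraries under 5000 transcripts and the fit with sample weights were chosen after seeing the data. No called change of a gene named by the rule, or of a list, reversed under any alternative run for it. List examples that the rule did not name were not run, and no single gene was run on untouched transcript rows. The balance between higher and lower calls turned under at least 1 alternative in 9 of 15 comparisons: M1 at 18 h, day 5 and day 7 and M2 at 18 h, day 3 and day 5 against monocytes (5 of 16, 7 of 17, 1 of 16, 9 of 16, 4 of 16 and 1 of 16 alternatives), day 7 against 18 h in M1 and M2 (5 and 1 of 17) and the interaction (1 of 25). It also turned for the calls of both arms at 18 h (3 of 3). For M2 at day 5 it went from 37 higher and 446 lower to 577 and 569 without the 6 libraries, and for M2 day 7 against 18 h from 14 and 68 to 138 and 81 after quantile normalization. Of the single-gene results 2490 were on the same side of the threshold, 134 lost (116 of them with the log2 change within 1.5 times of the main one) and 12 gained the call, and of the list results 466 stayed and 14 lost it. Where not stated the cause was not tested.

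A pseudocount of 1 made 114 of 139 called log2 changes of single genes smaller by over 1.5 times. With it, M2 at 18 h and day 3 against monocytes had 395 and 563 calls, M1 against M2 at day 5 had 22, the interaction 7, and 350 genes were called in both arms at 18 h. Without a filter M2 at 18 h and day 3 had 315 and 439, M1 against M2 at 18 h and day 5 had 22 and 30, and the interaction 2. A filter of 1 FPKM, which tests fewer genes, gave 838 for M1 at day 3, 98, 179 and 285 for M2 at 18 h, day 3 and day 7, and 6 for M1 against M2 at day 3. Quantile normalization gave 536 and 822 for M2 at 18 h and day 3, 566 and 219 for day 7 against 18 h in M1 and M2, 16, 16, 79 and 49 for M1 against M2 at the 4 times, and 435 called in both arms at 18 h. Rows as deposited gave 21 for M1 against M2 at day 5.

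The replicate number as a block gave 385 and 621 for M2 at 18 h and day 3 and 149 for M2 day 7 against 18 h, where the numbers did not pair the samples (pair correlations -0.03 to 0.00, -0.07 to 0.10 and -0.07 to 0.05). In the 2 comparisons with every pair's correlation over 0.1, it gave 503 against 463 (M2 day 7 against monocytes) and 8 against 10 (M1 against M2 at day 3). The block moved no other count by over 1.5 times and changed no call of a gene named by the rule. In no comparison did every sample correlate best with its own number. Fitting only the groups compared, with fewer samples, gave 605 and 643 for M1 at day 5 and day 7, 630, 1002, 118 and 182 for M2 at the 4 times, 52 for M2 day 7 against 18 h, and 4, 5 and 1 for M1 against M2 at 18 h, day 5 and day 7.

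Without the 6 libraries M2 had 1089, 1338, 1146 and 1169 calls against monocytes, day 7 against 18 h 795 (M1) and 262 (M2), and M1 against M2 29, 32, 21 and 39. Of these calls both arms shared 739 at 18 h and 810 at day 7. Sample weights gave 1490 and 1825 for M1 at 18 h and day 5, 1540, 1845, 1628 and 1850 for M2, 720 and 893 for day 7 against 18 h, 38, 116, 96 and 121 for M1 against M2, and 43 for the interaction.

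Leaving out 1 library at a time gave 48 to 124 calls for M2 at 18 h, 55 to 174 at day 3, 198 to 699 at day 5 and 169 to 495 at day 7. It gave 215 to 292 for M1 day 7 against 18 h and 26 to 243 for M2. For M1 against M2 it gave 5 to 11 at 18 h, 5 to 11 at day 3, 16 to 246 at day 5 and 7 to 69 at day 7, and for the interaction 1 to 2. For M1 against monocytes no left-out library moved a count by over 1.5 times (769 to 1489 over the 4 times).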

Other observations

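The tests of explanations in this part and the counts over other splits of the samples were all set after the results they bear on had been seen.

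Fewer genes were called in M2 than in M1 against monocytes at 18 h (181 against 979). Smaller changes in M2 are argued against by a regression slope of the M2 on the M1 log2 changes of 0.954. It was taken over the 3222 genes tested in both, with the variance between libraries removed, that of the shared monocytes included. No left-out range was computed for it. The first principal axis of the same changes had a slope of 0.971 (0.95 to 1.029 with each of 11 libraries left out), but the shared monocyte libraries draw it towards 1. Wider spread from the libraries with few detected transcripts is a candidate explanation: the median SE was 0.918 in the M2 fit and 0.605 in the M1 fit, and without the 6 libraries under 5000 transcripts M2 had 1089 calls and M1 1089, with 2 monocyte libraries left in each. What made those libraries list few transcripts was not tested, and no other biological explanation was tested.

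AL139099.5 stood at 0.000878 to 0.00203 FPKM in 5 libraries and at 3441 to 71506 in the other 32. The 5 were monocytes replicate 1, M1 18 h replicate 3, M1 day 3 replicate 1, M2 day 3 replicate 1 and M2 day 5 replicate 2. A state of the cells that differs between groups is argued against, since no group held more than 1 low library and the 5 lay in 5 groups. Both low day 3 libraries carry the same number, in a comparison where same-numbered samples deviated together. Whether low values follow a shared origin of the samples was not tested. No value decides on a graded difference in the amount of this RNA between libraries: 0 of the 37 libraries lay between these ranges, but the pattern was defined by that gap. On a row of 300 bp the highest low value would be 1 fragment in 1.64e+09, so it is no count of whole fragments unless a library was that deep, and the depth is unknown. Reads shared with near-identical copies may be assigned differently between runs, but no other copy is in the table, and the highest low value, 0.00203 FPKM, leaves this open.

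Other splits of the same samples were counted for each comparison, with the real split included. For M1 against monocytes no other split called as many genes as the real one. This was so at 18 h (1 of 35 splits, real 979, highest other 260) and day 3 (1 of 56, 1299 and 8). It was also so at day 5 (1 of 56, 1178 and 760) and day 7 (1 of 35, 1055 and 588). Nor did any other split for M2 against monocytes at 18 h (1 of 35, 181 and 36) or day 3 (1 of 35, 282 and 26). At day 5 in M2 it was 1 of 35 (483 and 380). How splits divided the libraries under 5000 transcripts was counted only where another split exceeded the real one. A part of these libraries in the counts against monocytes is therefore not excluded. Day 7 against 18 h gave 1 of 35 in M1 (372 and 2) and in M2 (82 and 1). Each of these shares is under 0.05, the smallest its splits can give, and not adjusted over the comparisons. For M1 against M2 at 18 h (1 of 35, 9 and 2) the splits cannot decide on chance. Its same-numbered samples correlated at 0.15, -0.03, 0.33 and 0.24, so some numbers may pair samples. Splits that part those pairs were not counted. Nor were such splits counted for M1 against M2 at day 5 (pair correlations 0.02 to 0.19) and day 7 (-0.04 to 0.3). In the 2 comparisons with every pair's correlation over 0.1, the counts over all splits ignore the pairs. They gave 1 of 35 for M2 at day 7 against monocytes (real 463, highest other 321) and 1 of 100 for M1 against M2 at day 3 (10 and 8). The splits that part as many pairs are 8 (real 463, highest other 125; 503 and 182 with the replicate block) and 16 (10 and 1; 8 and 8 with the block), which is too few for a share under 0.05. The others differ from the real split in which sample of a pair goes to which group. Chance cannot be excluded for the counts of M1 against M2 at day 5 (8 of 100; real 49, highest other 777), day 7 (2 of 35; 25 and 104) and for the interaction (6 of 100; 1 and 6). The splits with 777 and 104 calls, several times the real counts, point to a structure of the samples other than M1 and M2. They put all libraries under 5000 transcripts on 1 side: 3 at day 5 (M1 replicate 4 and M2 replicates 1 and 4) and 2 at day 7 (M2 replicates 3 and 4). Of the other splits that keep those libraries together, 7 of 20 at day 5 and 1 of 14 at day 7 called at least as many genes as the real one, and of those that part them 0 of 79 (highest 21) and 0 of 20 (highest 7).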
